A study of Homo sapiens with 4 samples.

How the data were processed

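RNA sequencing was done on clusters of A549 lung adenocarcinoma cells carrying a construct against DUSP23 (shDUSP23) or a control construct (shMock), with 2 libraries per group. Per the labels, total RNA was isolated, libraries were made with an mRNA kit and sequenced on an Illumina instrument. The deposited table gave FPKM (fragments scaled by transcript length in kilobases and by library size) computed by the authors, 1 value per Ensembl transcript and library, with no counts and no library totals. STAR 2.7.1a, DESeq2 1.32.0 and the GRCh38 build are named in the submitters' processing notes. The quantifier, its annotation release, the strandedness of the libraries and any filter on the listed transcripts are not given in the sources used here. The hairpin sequence, the number of hairpins, the batch of each library and the meaning of the suffix SUS in the sample titles are not given there either. Whether replicates were separate cultures is not stated, so p-values measure only the spread between these libraries.

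The table listed 56389 transcripts of 16371 genes, of which 13456 were protein-coding genes and 2052 lncRNA genes, and 83 transcripts had 0 in all libraries. Values were summed over the listed transcripts of each gene ID. This sum was decided after the table was seen, because the tests had been planned for gene values. Transcript lengths and GC content came from GENCODE release 29, which held 93.6% of the listed transcripts. In 2312 single-transcript genes most low FPKM values lay on equal steps, and the step and the transcript length gave the total number of fragments. With a tolerance of 0.1 fragment and values up to 50 fragments, 91.2%, 90.9%, 91.0% and 92.8% of these values were whole in shMock 1, shMock 2, shDUSP23 1 and shDUSP23 2. The totals were 21274400, 25243600, 26997200 and 42234200 fragments, and the size of 1 fragment sets the floor under low FPKM values. In genes with more than 1 listed transcript 74.5%, 73.0%, 74.9% and 81.4% of the sums were whole.

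Genes with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3, without rescaling and without covariates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are shDUSP23 minus shMock. The test, the thresholds, the 49 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were compared with the other genes by camera (limma) with its preset correlation of 0.01, and also with an estimated correlation and by fry, with Benjamini-Hochberg adjustment over 46 lists. Member counts are given over all genes and adjusted over the list alone. Named were DUSP23, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a group mean of at least 5 FPKM and no overlap between the groups, and the 4 members of each list with the smallest p. Other names, mainly members moving against their list, were chosen after their values were seen and put through the same alternatives. Some genes so chosen are not reported here.

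Alternatives chosen beforehand were pseudocounts of 0.1 and 1 FPKM, no filter and a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, eBayes without a trend and robust eBayes, the replicate number as a block, and leaving out each library in turn. Added after the table was seen were rescaling each library to the same sum of FPKM (TPM-type), transcripts as features, protein-coding transcripts alone, limma-voom on recovered fragments, and correction of each library for a spline (5 degrees of freedom) of GC content and length, with and without the block. Count models (edgeR, DESeq2), planned if whole reads could be had, were not run, since recovered values of genes with several transcripts were not all whole.

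The procedure was tested on simulated data, with errors drawn independently for each gene from the spread that limma fitted. Its false shares and list results need not hold where real genes vary together. Of 200 changed genes among 13691, limma recovered 3.0% of those at a log2 fold change of 0.5, 43.3% at 1 and 90.9% at 2, with 9 false among 100 calls. With 6161 changed genes it made 3391 calls, of which 2.5% were false. Camera with the preset correlation found 5 of 5 lists shifted by 0.5 and 0 of 35 others, and with an estimated correlation it found 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. All 4 libraries and every column with values were used.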

Results

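RNA sequencing libraries were made from cell clusters of A549, a human lung adenocarcinoma cell line, that carried either a short hairpin RNA against DUSP23 (shDUSP23) or a control construct (shMock). DUSP23 encodes a small dual-specificity protein phosphatase, and the study's title names chemoresistance and stem cell-like behaviour of non-small cell lung cancer cells as its subject. Each group had 2 libraries, numbered 1 and 2, and the labels did not say whether these came from separate cultures, so the p-values below measure only the spread between these libraries. The deposited FPKM values (fragments scaled by transcript length and library size) covered 56389 transcripts of 16371 genes. In genes with 1 listed transcript most low values, 90.9% to 92.8% per library, lay on steps of 1 fragment, and the step size gave 21274400 and 25243600 fragments for the shMock libraries and 26997200 and 42234200 for the shDUSP23 libraries. Over 13691 tested genes the Pearson correlation of log2 values was 0.99 between the shMock libraries and 0.97 between the shDUSP23 libraries, and it lay between 0.88 and 0.91 across the groups. Mitochondrially encoded transcripts held 12.3% and 13.1% of the summed FPKM in the shMock libraries and 8.12% and 7.97% in the shDUSP23 libraries.

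DUSP23 itself fell in the shDUSP23 clusters, and with it fell several liver-type secreted proteins, the mucin gene MUC5B, most listed genes of cell division and genes of ribosomes and respiration. TM4SF4, a tetraspanin-like membrane protein gene, fell from 76.3 ± 19.9 to 2.39 ± 1.52 FPKM, and FGB, which encodes the fibrinogen beta chain, fell from 251 ± 26.9 to 20.2 ± 0.39 FPKM (mean ± SD, n = 2 libraries per group here and throughout). CLDN4, a tight junction claudin gene, rose from 4.12 ± 0.54 to 77.2 ± 12.8 FPKM. The chemokine gene CCL5 rose from 2298 ± 15.1 to 7868 ± 449.5 FPKM. Many interferon-stimulated genes, class I HLA genes and several receptor tyrosine kinase and immediate early genes were also higher in shDUSP23, whereas ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, fell from 2839 ± 520.0 to 645 ± 40.8 FPKM. Of 26 tested stem-cell-like markers 12 fell and 7 rose, and the list did not stand apart from the other genes (camera, Benjamini-Hochberg adjusted p = 0.133).

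The targeted gene, DUSP23 (ENSG00000158716), lies on chromosome 1 of GRCh38 from 159780960 to 159782543 on the plus strand, and the table listed 2 protein-coding transcripts of it. Its level was 29.96 and 35.9 FPKM in the shMock libraries and 1.71 and 2.71 FPKM in the shDUSP23 libraries, 14.9 times lower by the group means. The fitted log2 fold change was -3.64 (SE 0.22; limma, Benjamini-Hochberg adjusted p = 3.12e-05), and both shDUSP23 libraries lay below both shMock libraries.

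Of the 13691 genes tested, 6202 changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, of which 3166 were higher and 3036 lower in shDUSP23. A change of at least 2-fold was met by 2501 of them, 1281 higher and 1220 lower. Leaving out shMock replicate 1 reduced the count of changed genes to 4038, and leaving out shMock replicate 2 reduced it to 3464. The listed FPKM summed to less in shDUSP23, so every library was also scaled to the same sum. The filter and pseudocount were applied anew to the scaled values, and 14951 genes were then tested. The median log2 fold change of all tested genes moved from 0.03 to 0.37. The share of higher genes among those changed moved from 51.0% to 76.2%. The fold changes given here are on the scale of log2(FPKM + 0.5) of the deposited values, which understates the change of genes with low values.

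**Figure D1:**
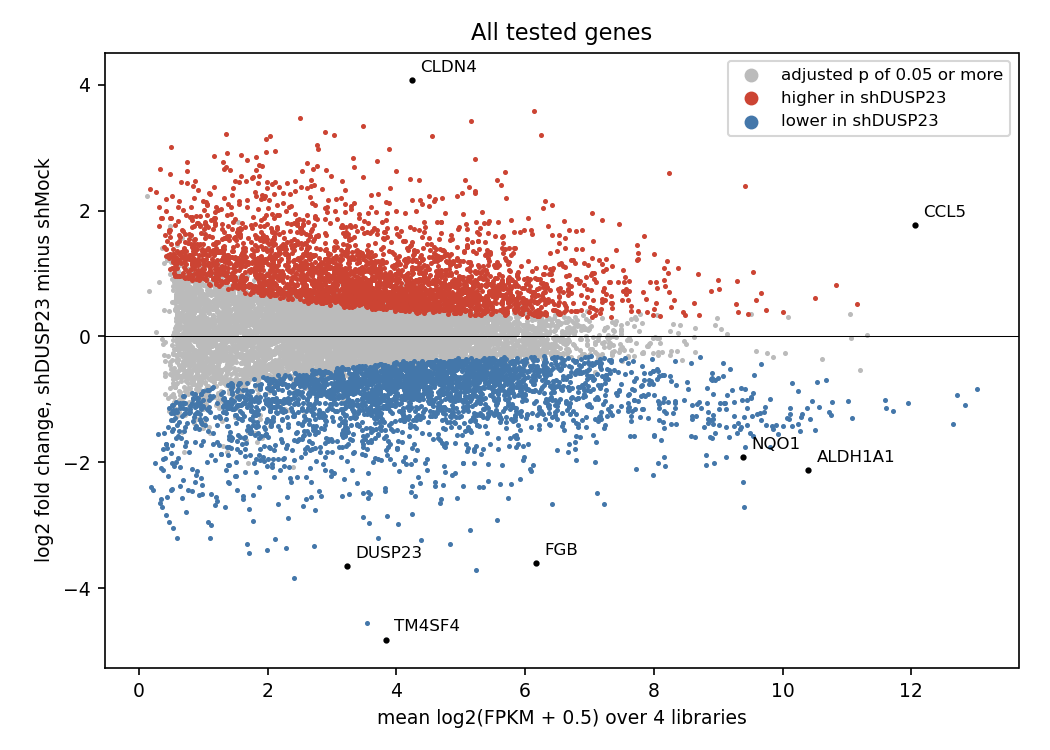
Each point is 1 of the 13691 tested genes, with its mean log2(FPKM + 0.5) over the 4 libraries on the x axis and its log2 fold change, shDUSP23 minus shMock, on the y axis. Red points (3166) were higher and blue points (3036) lower in shDUSP23 at an adjusted p under 0.05 in limma; 7 genes are labelled, with DUSP23 at -3.64.

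Among the 10 largest rises of genes with a group mean of at least 5 FPKM were CLDN4, HK2, CCL3L3, RRAD, KRT14, LINC00303, ITGAX, NUPR1 and AC020765.6. HK2, which encodes the glycolytic enzyme hexokinase 2, rose from 1.21 ± 0.0904 to 18.4 ± 2.75 FPKM (log2 fold change 3.47, SE 0.21). RRAD, a Ras-related GTPase gene, rose from 3.01 ± 0.3004 to 35.6 ± 7.74 FPKM (log2 fold change 3.35, SE 0.19). KRT14, a keratin of basal cells of stratified epithelia, rose from 1.93 ± 0.49 to 22.4 ± 2.42 FPKM (log2 fold change 3.25, SE 0.21). ITGAX, the integrin alpha X chain of myeloid cells, rose from 2.202 ± 0.0668 to 24.3 ± 0.94 FPKM (log2 fold change 3.20, SE 0.17), and the stress-induced regulator gene NUPR1 rose from 24.6 ± 2.95 to 229.6 ± 27.4 FPKM (log2 fold change 3.19, SE 0.14). AC020765.6 overlaps NUPR1 on the same strand of chromosome 16, so its rise from 7.297 ± 0.6985 to 70.8 ± 10.9 FPKM may not be separable from that of NUPR1. The noncoding RNA LINC00303 rose from 0.34 ± 0.00906 to 7.38 ± 1.52 FPKM. CCL3L3, a near copy of the chemokine gene CCL3, rose from 10.7 ± 3.64 to 119.8 ± 40.4 FPKM, and how the authors' counting divided reads between such copies is uncertain.

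The 10 largest falls were those of TM4SF4, SERPINA3, H2AC18, FGG, DUSP23, FGB, FAM83D, NUF2, GMNN and AL163636.1. SERPINA3, the acute-phase protease inhibitor alpha-1-antichymotrypsin, fell from 56.1 ± 5.403 to 2.004 ± 0.91 FPKM (log2 fold change -4.54, SE 0.24). FGG and FGB, which with FGA form the fibrinogen cluster of chromosome 4, fell by 3.71 (SE 0.18) and 3.60 (SE 0.12) on the log2 scale. NUF2, a kinetochore component, fell from 12.4 ± 1.03 to 0.76 ± 0.43 FPKM (log2 fold change -3.39, SE 0.28). Of the others, 4 were listed at 0 in 1 shDUSP23 library, so their rank rests on that library. Transcripts at 0 numbered 2930 and 4334 in the shMock libraries and 4814 and 9946 in the shDUSP23 libraries, the most in the library with the most fragments. FAM83D, a spindle protein gene, had 11.6 and 9.19 FPKM in shMock against 0 and 1.49 FPKM in shDUSP23. GMNN, which encodes the replication licensing inhibitor geminin, had 13.6 and 16.5 FPKM in shMock against 4.11 and 0 FPKM in shDUSP23. The histone gene H2AC18, which has a near-identical copy, had 21.6 and 17.7 FPKM against 0 and 3.41 FPKM. AL163636.1, which overlaps ANG and RNASE4, had 13.8 and 30.3 FPKM against 8.13 and 0 FPKM. Robust eBayes ended the calls of H2AC18, GMNN and AL163636.1 (limma, Benjamini-Hochberg adjusted p = 0.104, 0.153 and 0.292). GMNN and AL163636.1 also lost their calls when either shMock library was left out, with limma Benjamini-Hochberg adjusted p = 0.0572 and 0.0691 for GMNN and 0.0788 and 0.175 for AL163636.1. AL163636.1 lost its call also with a pseudocount of 0.1 FPKM (adjusted p = 0.056), without a filter (0.0531), without a trend (0.0917) and after correction for GC content and length (0.0571). Without the shDUSP23 library listed at 0 the log2 fold change was -1.75 for GMNN, -1.28 for AL163636.1, -2.36 for H2AC18 and -2.45 for FAM83D, and without the other one it was -4.95, -5.39, -5.32 and -4.44.

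**Figure D2:**
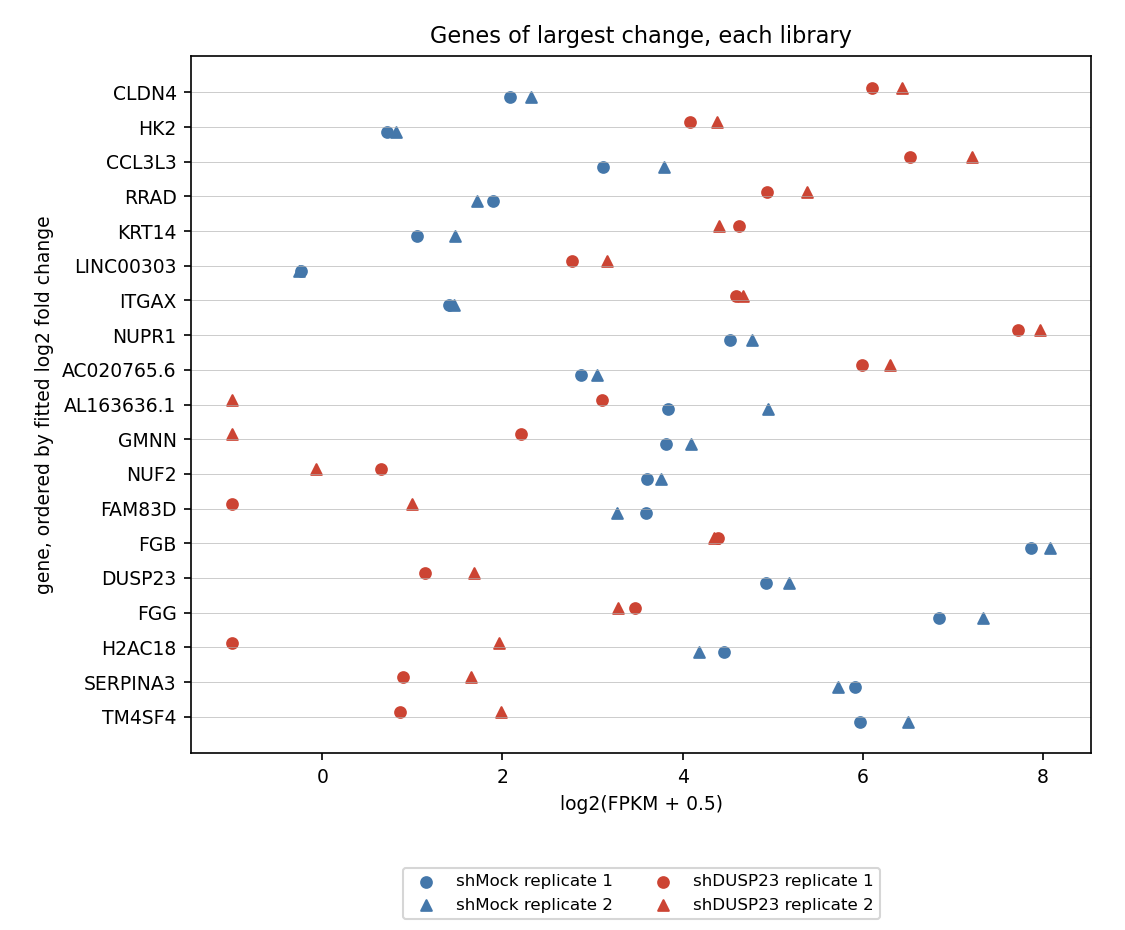
Points give log2(FPKM + 0.5) of each library for 9 of the 10 genes with the largest rise and the 10 with the largest fall, ordered by fitted log2 fold change, with shMock in blue and shDUSP23 in red, circles for replicate 1 and triangles for replicate 2. In all 19 genes shown both shDUSP23 libraries lie on the same side of both shMock libraries, as the rule that picked the genes required. A value of 0 FPKM sits at the left edge.

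Gene groups were compared through 49 lists fixed before the data were examined, 46 of which had at least 5 tested members, and 25 of these stood apart from the other genes in camera, 14 toward lower and 11 toward higher values. With a correlation between genes estimated from these libraries, which leave 2 residual degrees of freedom, 0 of the 46 lists passed. At an unadjusted p this stricter form of camera called 3 lists under 0.05, and fry, which asks only whether the members of a list moved on balance in 1 direction, called 26 at an adjusted p under 0.05. The counts of members below are also given with every library scaled to the same sum (equal sums) and after correction of each library for the GC content and length of transcripts (GC correction). On simulated libraries with 5 shifted lists, camera with its preset correlation found all 5 and the estimated correlation found 0. Genes varied independently in that simulation, whereas the estimated correlation in the real lists reached 0.827 (cytosolic ribosomal proteins). It therefore cannot show how often the preset form calls lists wrongly where members vary together.

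Most genes of the cell division lists fell. In the list of G2 and M phase genes 0 rose and 34 fell of 35 tested members (0 and 34 adjusted over the list alone, 0 and 32 with equal sums, 0 and 35 after GC correction). For G2/M genes, camera gave a Benjamini-Hochberg adjusted p = 5.96e-16, and adjusted p = 0.514 with an estimated correlation. PTTG1, the securin that holds back chromosome separation, fell from 49.98 ± 6.81 to 6.66 ± 0.99 FPKM (log2 fold change -2.82). TOP2A, DNA topoisomerase II alpha, fell from 59.5 ± 7.88 to 11.2 ± 0.56 FPKM (log2 fold change -2.35). CCNB1, cyclin B1, fell from 73.7 ± 2.796 to 18.02 ± 3.57 FPKM (log2 fold change -2.02). CDC25B, the member that did not pass, had 86.7 and 73.6 FPKM. Among G1 and S phase genes 0 rose and 27 fell of 34 tested members (0 and 28 adjusted over the list alone, 0 and 17 with equal sums, 0 and 28 after GC correction). For G1/S genes, camera gave a Benjamini-Hochberg adjusted p = 1.79e-09, and adjusted p = 0.514 with an estimated correlation. PCNA, the sliding clamp of DNA replication, fell from 328 ± 5.595 to 58.1 ± 2.82 FPKM (log2 fold change -2.49). RRM2, a ribonucleotide reductase subunit, fell from 24.6 ± 3.91 to 5.73 ± 0.0885 FPKM. In the DNA repair list 5 rose and 23 fell of 50 tested members (6 and 26 adjusted over the list alone, 7 and 10 with equal sums, 6 and 24 after GC correction). For DNA repair, camera gave a Benjamini-Hochberg adjusted p = 0.00154, and adjusted p = 0.514 with an estimated correlation. APEX1, the base excision repair endonuclease, fell from 114 ± 1.59 to 49.9 ± 2.54 FPKM (log2 fold change -1.18). ATM, the kinase that signals double-strand breaks, fell from 21.4 ± 1.71 to 10.5 ± 1.15 FPKM. CHEK1, a checkpoint kinase, fell from 20.3 ± 0.86 to 9.204 ± 0.32 FPKM (log2 fold change -1.10). The 5 that rose were LIG1, XPA, XPC, RAD51D and ERCC6, and XPC, a damage sensor of nucleotide excision repair, rose from 20.1 ± 1.04 to 33.1 ± 0.99 FPKM. The DNA repair median was -0.50, and -0.17 with equal sums, where the median of all tested genes moved from 0.03 to 0.37.

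Most members of the ribosomal protein and respiration lists fell. Of the cytosolic ribosomal protein genes 0 rose and 56 fell of 56 tested members (0 and 56 adjusted over the list alone, 0 and 53 with equal sums, 0 and 56 after GC correction), with a median log2 fold change of -1.26. For cytosolic ribosomal proteins, camera gave a Benjamini-Hochberg adjusted p = 1.32e-24, and adjusted p = 0.551 with an estimated correlation. RPS20 fell from 1260.2 ± 102 to 371 ± 33.9 FPKM (log2 fold change -1.76). RPL3 fell from 697 ± 73.98 to 229.7 ± 5.802 FPKM (log2 fold change -1.60). RPS24 fell from 1654 ± 209 to 486 ± 28.9 FPKM (log2 fold change -1.76); these genes have many processed pseudogenes, and the division of reads between them is uncertain. Among nuclear genes of oxidative phosphorylation (OXPHOS) 1 rose and 34 fell of 44 tested members (1 and 35 adjusted over the list alone, 1 and 26 with equal sums, 1 and 32 after GC correction). For OXPHOS nuclear genes, camera gave a Benjamini-Hochberg adjusted p = 2.99e-11, and adjusted p = 0.556 with an estimated correlation. ATP5F1C, a subunit of ATP synthase, fell from 203 ± 26.1 to 58.2 ± 5.39 FPKM (log2 fold change -1.79). COX7C, a cytochrome c oxidase subunit, rose from 122 ± 20.9 to 193 ± 0.31 FPKM (log2 fold change 0.68). Of the mitochondrially encoded genes 1 rose and 14 fell of 15 tested members (1 and 14 adjusted over the list alone, 1 and 14 with equal sums, 1 and 13 after GC correction). For mitochondrially encoded genes, camera gave a Benjamini-Hochberg adjusted p = 8.26e-07, and adjusted p = 0.53 with an estimated correlation. MT-CO3 fell from 10457 ± 1489 to 3954 ± 105.02 FPKM (log2 fold change -1.40). MT-ND6 fell from 140.2 ± 6.01 to 33.8 ± 3.93 FPKM (log2 fold change -2.04), and the ribosomal RNA gene MT-RNR1 rose from 1917 ± 231 to 2743 ± 171 FPKM (log2 fold change 0.52). Across all tested genes, which are not independent replicates, log2 fold change went with the GC content of transcripts (Spearman's rho 0.27) and less with their length (0.14). Trends of this size also lay between libraries of the same group. For replicate 2 minus replicate 1, rho with GC content was 0.27 in shDUSP23 and 0.13 in shMock, and rho with length was -0.03 and -0.31. After correction of each library for GC content and length, the medians of the ribosomal protein, OXPHOS and mitochondrial lists were -1.08, -0.61 and -0.64. They were -1.26, -0.85 and -1.06 before it and -0.51, -0.60 and -0.37 with quantile normalization.

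In the drug response groups, targets of NRF2, the transcription factor of the antioxidant response, were mostly lower. In that list 1 rose and 23 fell of 32 tested members (1 and 24 adjusted over the list alone, 5 and 20 with equal sums, 0 and 23 after GC correction). For NRF2 targets, camera gave a Benjamini-Hochberg adjusted p = 8.13e-08, and adjusted p = 0.514 with an estimated correlation. NQO1, a quinone reductase, fell from 1303 ± 73.1 to 344 ± 18.5 FPKM (log2 fold change -1.92). AKR1B10, an aldo-keto reductase, fell from 1507 ± 284 to 302 ± 26.4 FPKM (log2 fold change -2.31). AKR1C2 fell from 1741 ± 390.2 to 264 ± 16.9 FPKM (log2 fold change -2.70), with the reservation that its sequence is close to those of AKR1C1 and AKR1C3. OSGIN1, the 1 member that rose, went from 14.1 ± 1.101 to 21.9 ± 0.0608 FPKM (log2 fold change 0.62). Among genes of drug metabolism and detoxification 6 rose and 18 fell of 31 tested members (6 and 18 adjusted over the list alone, 8 and 15 with equal sums, 5 and 19 after GC correction). For drug metabolism and detoxification, camera gave a Benjamini-Hochberg adjusted p = 0.0041, and adjusted p = 0.514 with an estimated correlation. MGST1, a microsomal glutathione transferase, fell from 529 ± 52.1 to 201 ± 12.5 FPKM (log2 fold change -1.39). TYMS, the thymidylate synthase targeted by fluoropyrimidines, fell from 48.3 ± 7.34 to 18.4 ± 2.28 FPKM (log2 fold change -1.37). CDA, cytidine deaminase, rose from 16.00 ± 0.19 to 50.01 ± 6.198 FPKM (log2 fold change 1.61). UGT1A7 fell from 22.3 ± 0.83 to 3.52 ± 0.0718 FPKM (log2 fold change -2.50), but the UGT1A genes share exons and are uncertain one by one.

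The drug efflux transporters and the stem-cell-like markers did not stand apart as groups. For efflux transporters 3 rose and 3 fell of 14 tested members (3 and 3 adjusted over the list alone, 5 and 2 with equal sums, 0 and 5 after GC correction) (camera, Benjamini-Hochberg adjusted p = 0.737). ABCC2 and ABCC3, which carry drug conjugates out of the cell, fell from 191 ± 14.6 to 108 ± 2.32 FPKM and from 196 ± 22.1 to 117 ± 12.1 FPKM, and the other member that fell was ABCC4. The 3 that rose were MVP, ABCA2 and ABCC5, with the vault protein gene MVP rising from 64.4 ± 2.73 to 89.2 ± 12.2 FPKM. MVP lost its call after correction for GC content and length (limma, Benjamini-Hochberg adjusted p = 0.344) and without shMock replicate 1 (0.0987), shMock replicate 2 (0.0603) or shDUSP23 replicate 2 (0.117). ABCC4 lost its call with equal sums (adjusted p = 0.377) and without shMock replicate 1 (0.0887), shMock replicate 2 (0.183) or shDUSP23 replicate 2 (0.0673). ABCG2, a marker of side population cells, had 6.496 and 7.38 FPKM and did not pass. Among stem-cell-like markers 7 rose and 12 fell of 26 tested members (7 and 13 adjusted over the list alone, 7 and 9 with equal sums, 6 and 12 after GC correction) (camera, Benjamini-Hochberg adjusted p = 0.133). ALDH1A1 fell by 2.13 and ALDH3A1 by 1.45 on the log2 scale. NOTCH3, a Notch receptor, fell from 24.7 ± 3.81 to 8.56 ± 1.16 FPKM (log2 fold change -1.47). SOX2, a pluripotency factor, fell from a low level, from 2.24 ± 0.45 to 0.46 ± 0.0679 FPKM. CD44, the hyaluronan receptor, rose from 375 ± 7.04 to 702 ± 25.7 FPKM (log2 fold change 0.91). The median of this list, -0.50, was -0.01 when libraries were scaled to the same sum, where the median of all genes was 0.37.

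In the lists of receptor and mitogen-activated protein kinase (MAPK) signalling more members rose than fell. In the family of dual-specificity phosphatases, from which DUSP23 itself had been left out, 13 rose and 1 fell of 23 tested members (13 and 1 adjusted over the list alone, 17 and 0 with equal sums, 10 and 1 after GC correction). For dual-specificity phosphatase family, camera gave a Benjamini-Hochberg adjusted p = 0.00216, and adjusted p = 0.53 with an estimated correlation. DUSP5, a nuclear phosphatase of ERK, rose from 65.5 ± 10.7 to 211 ± 0.31 FPKM (log2 fold change 1.69). DUSP22 rose from 5.55 ± 0.49 to 19.7 ± 2.91 FPKM (log2 fold change 1.73). PTPMT1, a mitochondrial lipid phosphatase and the 1 member lower, fell from 19.8 ± 2.25 to 14.6 ± 0.44 FPKM (log2 fold change -0.43). Among output genes of the ERK pathway 13 rose and 3 fell of 23 tested members (13 and 3 adjusted over the list alone, 17 and 2 with equal sums, 13 and 3 after GC correction). For ERK pathway output genes, camera gave a Benjamini-Hochberg adjusted p = 0.0041, and adjusted p = 0.609 with an estimated correlation. FOSL1, an AP-1 subunit, rose from 18.5 ± 2.64 to 61.5 ± 6.75 FPKM (log2 fold change 1.71). HBEGF, an EGF receptor ligand, rose from 3.44 ± 0.85 to 13.7 ± 0.99 FPKM (log2 fold change 1.87). The 3 that fell were ETV1, FOS and AREG, another ligand of that receptor, which fell from 32.02 ± 4.702 to 14.4 ± 4.099 FPKM (log2 fold change -1.15). Among stress MAPK and immediate early genes 12 rose and 4 fell of 23 tested members (14 and 4 adjusted over the list alone, 17 and 0 with equal sums, 9 and 5 after GC correction). For stress MAPK and immediate early genes, camera gave a Benjamini-Hochberg adjusted p = 0.00276, and adjusted p = 0.598 with an estimated correlation. JUN rose from 57.2 ± 7.25 to 169 ± 11.02 FPKM (log2 fold change 1.56). KLF6 rose from 37.9 ± 7.395 to 157 ± 2.34 FPKM (log2 fold change 2.05). The 4 that fell were GADD45B, NR4A1, KLF10 and FOS, with FOS falling from 10.1 ± 1.47 to 6.77 ± 0.0901 FPKM (log2 fold change -0.53). Of receptor tyrosine kinases and their ligands 17 rose and 2 fell of 28 tested members (17 and 2 adjusted over the list alone, 19 and 2 with equal sums, 14 and 6 after GC correction). For receptor tyrosine kinases and ligands, camera gave a Benjamini-Hochberg adjusted p = 0.00216, and adjusted p = 0.556 with an estimated correlation. AXL rose from 22.6 ± 4.34 to 64.7 ± 0.33 FPKM (log2 fold change 1.51). EPHA2 rose from 27.1 ± 3.27 to 68.97 ± 5.34 FPKM (log2 fold change 1.33). The 2 that fell were AREG and FGFR4, with FGFR4 falling from 27.8 ± 0.95 to 13.7 ± 2.24 FPKM.

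**Figure D3:**
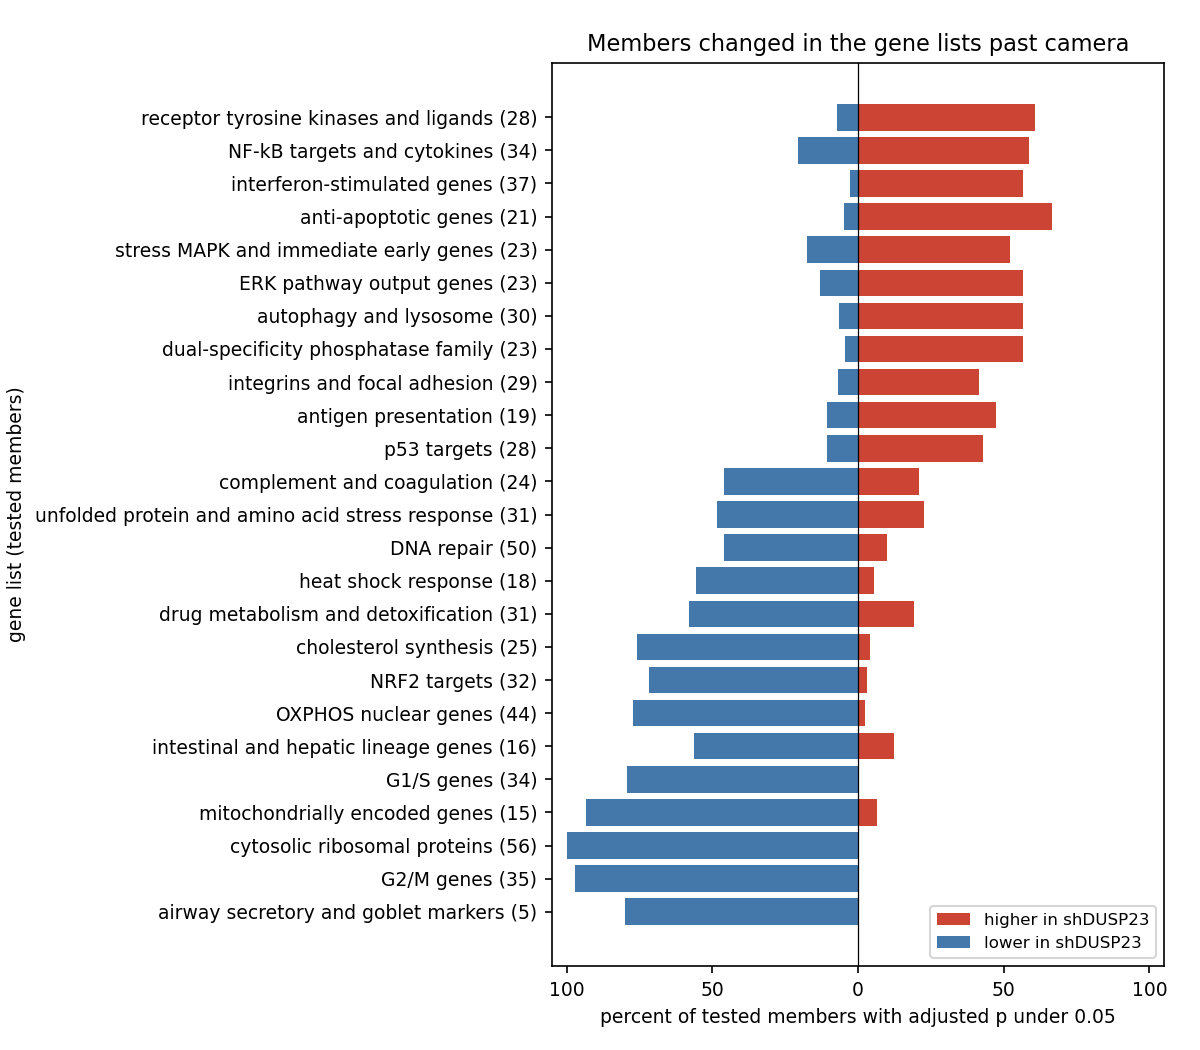
Bars show, for each of the 25 gene lists past camera, the percent of tested members that were higher (red, to the right) or lower (blue, to the left) in shDUSP23 at an adjusted p under 0.05 in limma, with the number of tested members beside each name and lists ordered by median log2 fold change. All 56 cytosolic ribosomal protein genes and 34 of 35 G2/M genes lie on the lower side, and 0 of the 25 lists stayed past camera with an estimated correlation.

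In the innate immune lists more members rose than fell. Among interferon-stimulated genes 21 rose and 1 fell of 37 tested members (22 and 2 adjusted over the list alone, 28 and 0 with equal sums, 22 and 0 after GC correction). For interferon-stimulated genes, camera gave a Benjamini-Hochberg adjusted p = 1.36e-05, and adjusted p = 0.58 with an estimated correlation. RSAD2, the antiviral enzyme viperin, rose from 123 ± 14.9 to 741 ± 34.4 FPKM (log2 fold change 2.59). DHX58, which regulates the sensing of viral RNA, rose from 43.99 ± 0.58 to 149.6 ± 0.0982 FPKM (log2 fold change 1.75). IFIT1, the 1 member lower, fell from 366 ± 18.7 to 281 ± 31.4 FPKM (log2 fold change -0.38). Among NF-kB targets and cytokines 20 rose and 7 fell of 34 tested members (21 and 7 adjusted over the list alone, 22 and 6 with equal sums, 20 and 7 after GC correction). For NF-kB targets and cytokines, camera gave a Benjamini-Hochberg adjusted p = 0.0066, and adjusted p = 0.58 with an estimated correlation. CCL5 rose by a log2 fold change of 1.77. CSF1, the macrophage growth factor, rose from 16.5 ± 1.92 to 82.3 ± 12.4 FPKM (log2 fold change 2.28). TRAF1, a signalling adaptor of TNF receptors, rose from 28.7 ± 2.57 to 104 ± 8.303 FPKM (log2 fold change 1.84). The neutrophil chemokine gene CXCL5 fell from 594 ± 99.01 to 143 ± 24.9 FPKM (log2 fold change -2.06). This list did not pass camera on recovered fragments (limma-voom, Benjamini-Hochberg adjusted p = 0.0751). Of the antigen presentation genes 9 rose and 2 fell of 19 tested members (10 and 2 adjusted over the list alone, 15 and 1 with equal sums, 11 and 2 after GC correction). For antigen presentation, camera gave a Benjamini-Hochberg adjusted p = 0.0069, and adjusted p = 0.522 with an estimated correlation. The class I genes HLA-C and HLA-E, which are alike in sequence, rose from 72.4 ± 11.4 to 191 ± 26.4 FPKM and from 47.9 ± 7.56 to 98.8 ± 0.28 FPKM. The 2 that fell were HLA-DMA and HLA-DMB, which together load peptides on class II molecules, with HLA-DMB falling from 26.3 ± 6.99 to 4.29 ± 1.35 FPKM (log2 fold change -2.49).

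In the sterol and chaperone lists more members fell than rose, and in the lysosomal list more rose than fell. Of the cholesterol synthesis genes 1 rose and 19 fell of 25 tested members (1 and 20 adjusted over the list alone, 1 and 12 with equal sums, 0 and 18 after GC correction). For cholesterol synthesis, camera gave a Benjamini-Hochberg adjusted p = 2.59e-06, and adjusted p = 0.514 with an estimated correlation. FDFT1, squalene synthase, fell from 114 ± 1.16 to 34.1 ± 5.603 FPKM (log2 fold change -1.74). MVK, mevalonate kinase, fell from 14.6 ± 0.28 to 4.87 ± 0.27 FPKM (log2 fold change -1.49). In the heat shock list 1 rose and 10 fell of 18 tested members (2 and 10 adjusted over the list alone, 3 and 8 with equal sums, 1 and 11 after GC correction). For heat shock response, camera gave a Benjamini-Hochberg adjusted p = 0.00223, and adjusted p = 0.53 with an estimated correlation. The chaperone genes HSP90AA1 and HSPD1 fell from 552 ± 5.53 to 146 ± 4.27 FPKM and from 359 ± 9.36 to 119 ± 1.78 FPKM. HSPB1, a small heat shock protein gene, rose from 145 ± 3.19 to 245 ± 14.7 FPKM (log2 fold change 0.76). In the list of the unfolded protein and amino acid stress response 7 rose and 15 fell of 31 tested members (7 and 15 adjusted over the list alone, 8 and 11 with equal sums, 6 and 16 after GC correction). For unfolded protein and amino acid stress response, camera gave a Benjamini-Hochberg adjusted p = 0.0129, and adjusted p = 0.53 with an estimated correlation. The members moved apart: the endoplasmic reticulum chaperone gene HSP90B1 fell from 445 ± 22.8 to 148 ± 6.41 FPKM (log2 fold change -1.58), and the stress transcription factor genes DDIT3 and ATF3 rose from 68.7 ± 9.63 to 179.9 ± 24.5 FPKM and from 129 ± 29.7 to 266 ± 38.9 FPKM. The list's call was lost with quantile normalization (camera, Benjamini-Hochberg adjusted p = 0.0686) and on recovered fragments (adjusted p = 0.138). Its median of -0.34 was 0 with libraries scaled to the same sum, where the median of all tested genes moved from 0.03 to 0.37. Of the autophagy and lysosome genes 17 rose and 2 fell of 30 tested members (20 and 2 adjusted over the list alone, 23 and 2 with equal sums, 17 and 2 after GC correction). For autophagy and lysosome, camera gave a Benjamini-Hochberg adjusted p = 0.000592, and adjusted p = 0.556 with an estimated correlation. CTSB, a lysosomal protease, rose from 137 ± 13.6 to 344 ± 53.1 FPKM. TFE3, a transcription factor of lysosomal genes, rose from 30.9 ± 1.83 to 55.6 ± 0.62 FPKM (log2 fold change 0.84). The 2 that fell were GLA and ATP6V0D1, a subunit of the proton pump, which fell from 26.4 ± 3.27 to 12.4 ± 0.12 FPKM (log2 fold change -1.05).

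In the lists of secretory and hepatic identity more members fell than rose. Of the 5 tested airway secretory and goblet markers 0 rose and 4 fell (0 and 4 adjusted over the list alone, 0 and 4 with equal sums, 0 and 4 after GC correction). For airway secretory and goblet markers, camera gave a Benjamini-Hochberg adjusted p = 0.00371, and adjusted p = 0.522 with an estimated correlation. MUC5B fell from 66.8 ± 28.8 to 6.46 ± 1.84 FPKM (log2 fold change -3.23). AGR2, a disulfide isomerase needed for mucin folding, fell from 388 ± 124 to 59.3 ± 0.5046 FPKM (log2 fold change -2.66). Among intestinal and hepatic lineage genes 2 rose and 9 fell of 16 tested members (2 and 9 adjusted over the list alone, 3 and 8 with equal sums, 2 and 10 after GC correction). For intestinal and hepatic lineage genes, camera gave a Benjamini-Hochberg adjusted p = 0.00276, and adjusted p = 0.514 with an estimated correlation. CPS1, the urea cycle carbamoyl phosphate synthetase, fell from 102 ± 11.1 to 24.1 ± 2.15 FPKM (log2 fold change -2.05). FGA fell from 130.1 ± 9.75 to 16.8 ± 0.16 FPKM (log2 fold change -2.91). The 2 that rose were the transcription factor genes FOXA1 and GATA6, with GATA6 rising from 3.15 ± 0.56 to 7.46 ± 0.33 FPKM (log2 fold change 1.13). In the complement and coagulation list, which shares the fibrinogen genes and SERPINA1 with the hepatic list, 5 rose and 11 fell of 24 tested members (5 and 11 adjusted over the list alone, 7 and 9 with equal sums, 4 and 10 after GC correction). For complement and coagulation, camera gave a Benjamini-Hochberg adjusted p = 0.00989, and adjusted p = 0.514 with an estimated correlation. The 5 that rose were CLU, PLAU, CFB, C4A and C3, with C3 rising from 95.2 ± 1.17 to 162 ± 24.2 FPKM (log2 fold change 0.76). That list did not pass camera with quantile normalization (Benjamini-Hochberg adjusted p = 0.0654). Its median of -0.28 was 0.05 with libraries scaled to the same sum, where the median of all tested genes moved from 0.03 to 0.37.

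In the adhesion, survival and p53 target lists more members rose than fell. Among integrins and focal adhesion genes 12 rose and 2 fell of 29 tested members (15 and 2 adjusted over the list alone, 19 and 2 with equal sums, 9 and 5 after GC correction). For integrins and focal adhesion, camera gave a Benjamini-Hochberg adjusted p = 0.00772, and adjusted p = 0.619 with an estimated correlation. ITGA5, the fibronectin receptor alpha chain, rose from 51.6 ± 9.67 to 185 ± 16.6 FPKM (log2 fold change 1.84). ZYX rose from 31.9 ± 5.201 to 69.1 ± 6.28 FPKM (log2 fold change 1.11). The 2 that fell were ITGA1 and ITGB1, with ITGB1 falling from 607 ± 23.6 to 377 ± 1.25 FPKM (log2 fold change -0.69). The list did not pass after correction for GC content and length (camera, Benjamini-Hochberg adjusted p = 0.162). Of the anti-apoptotic genes 14 rose and 1 fell of 21 tested members (14 and 2 adjusted over the list alone, 15 and 1 with equal sums, 12 and 4 after GC correction). For anti-apoptotic genes, camera gave a Benjamini-Hochberg adjusted p = 0.00875, and adjusted p = 0.556 with an estimated correlation. CFLAR, an inhibitor of death receptor signalling, rose from 66.4 ± 1.51 to 143 ± 3.27 FPKM (log2 fold change 1.10). TNFAIP3 rose from 97.7 ± 12.8 to 183 ± 5.57 FPKM (log2 fold change 0.91). BIRC5, survivin, which also acts in mitosis, fell from 17.3 ± 1.39 to 8.07 ± 1.95 FPKM (log2 fold change -1.07). Among p53 targets 12 rose and 3 fell of 28 tested members (12 and 3 adjusted over the list alone, 17 and 0 with equal sums, 11 and 4 after GC correction). For p53 targets, camera gave a Benjamini-Hochberg adjusted p = 0.0168, and adjusted p = 0.58 with an estimated correlation. BTG2, an antiproliferative gene, rose from 7.01 ± 0.34 to 26.6 ± 0.43 FPKM (log2 fold change 1.85). CDKN1A, the cell cycle inhibitor p21, rose from 128 ± 0.26 to 235 ± 20.9 FPKM (log2 fold change 0.87). FAS rose from 34.5 ± 0.96 to 85.5 ± 2.26 FPKM (log2 fold change 1.30). The 3 that fell were TP53I3, FDXR and BAX, with BAX falling from 114 ± 3.55 to 90.3 ± 5.57 FPKM (log2 fold change -0.34).

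Members named because they moved against their list, together with the markers CD44, SOX2 and ABCG2 and the stress genes DDIT3 and ATF3, were chosen after their values were seen. Of all 75 called genes chosen in this way, those of the closing section and others included, 30 kept their call whichever library was left out, 12 lost it under 1 of the 4 omissions, 14 under 2, 15 under 3 and 4 under all 4 (limma, Benjamini-Hochberg adjusted p of 0.05 or more). Those that lost it under all 4 were BAX, C4A, FOS and PTPMT1. Those under 3 were ABCA2, ABCC5, CDK4, CDKN1B, ERCC6, FDXR, GADD45B, HES6, HLA-DMA, JAK2, KRT7, PHC2, S100A4, TP53I3 and XPA. IFIT1, MT-RNR1, ITGA1, ETV1 and KLF10 were among those under 2, and OSGIN1, SOX2, LIG1, NR4A1 and RAD51D among those under 1. With equal sums 22 of the 75 lost their call, among them BAX, FDXR and TP53I3 of the p53 targets, FOS, GADD45B, KLF10 and NR4A1 of the stress list, PTPMT1 and IFIT1, and after GC correction 13 did. With protein-coding transcripts alone the calls of ERCC6, XPA and RAD51D were lost (adjusted p = 0.483, 0.149 and 0.0984). With quantile normalization IFIT1 and ITGB1 lay on the higher side without passing (limma, Benjamini-Hochberg adjusted p = 0.707 and 0.767). LIG1 fell rather than rose when protein-coding transcripts alone were counted (limma, Benjamini-Hochberg adjusted p = 0.0213).

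In the following lists, which did not pass camera, members moved both ways. Among glycolysis genes 6 rose and 10 fell of 21 tested members (6 and 10 adjusted over the list alone, 7 and 7 with equal sums, 6 and 13 after GC correction) (camera, Benjamini-Hochberg adjusted p = 0.259). SLC2A3, a glucose transporter gene, rose from 20.3 ± 1.48 to 127 ± 22.1 FPKM. LDHB, lactate dehydrogenase B, fell from 990.1 ± 185 to 242 ± 3.54 FPKM. Of the hypoxia response genes 14 rose and 8 fell of 28, or 14 and 8 adjusted over the list alone (15 and 5 with equal sums, 15 and 8 after GC correction). VEGFA rose from 26.04 ± 0.22 to 64.6 ± 0.81 FPKM (log2 fold change 1.29). Of the epithelial genes 6 rose and 5 fell (CDH1, CLDN2, EPCAM, KRT18 and KRT7) of 19, or 6 and 5 adjusted over the list alone (8 and 2 with equal sums, 4 and 7 after GC correction). CDH1, E-cadherin, fell from 21.96 ± 0.63 to 7.17 ± 1.37 FPKM (log2 fold change -1.56). Of the mesenchymal genes 10 rose and 4 fell (COL4A2, FN1, S100A4 and SERPINE2) of 23, or 10 and 4 adjusted over the list alone (11 and 3 with equal sums, 9 and 6 after GC correction). COL5A1, a collagen chain, rose from 1.78 ± 0.25 to 12.5 ± 4.18 FPKM. FN1, fibronectin, fell from 129 ± 15.6 to 21.5 ± 4.47 FPKM. Of the extracellular matrix and protease genes 14 rose and 8 fell of 32, or 17 and 9 adjusted over the list alone (19 and 6 with equal sums, 12 and 8 after GC correction). LAMB3, a laminin chain, rose from 20.98 ± 1.76 to 114 ± 17.8 FPKM (log2 fold change 2.41). Of Wnt/beta-catenin targets 8 rose and 4 fell (DKK1, MMP7, RNF43 and ZNRF3) of 18, or 8 and 4 adjusted over the list alone (10 and 2 with equal sums, 6 and 6 after GC correction). Of TGF-beta targets 10 rose and 3 fell (ID1, ID3 and SMAD6) of 22, or 11 and 3 adjusted over the list alone (14 and 2 with equal sums, 8 and 5 after GC correction). Of YAP/TEAD targets 10 rose and 4 fell (CRIM1, F3, GADD45B and IGFBP3) of 22, or 10 and 4 adjusted over the list alone (13 and 3 with equal sums, 10 and 5 after GC correction). Of NOTCH pathway genes 2 rose (DTX4 and HES6) and 4 fell (HES1, JAG1, NOTCH3 and NRARP) of 16, or 2 and 4 adjusted over the list alone (5 and 4 with equal sums, 1 and 4 after GC correction). Of JAK-STAT3 axis genes 9 rose and 4 fell (FGA, FGB, FGG and JAK2) of 20, or 9 and 5 adjusted over the list alone (12 and 3 with equal sums, 10 and 4 after GC correction). Of pro-apoptotic genes 9 rose and 2 fell (BAX and CYCS) of 26, or 9 and 2 adjusted over the list alone (15 and 1 with equal sums, 10 and 3 after GC correction). Of CDK inhibitors and cyclins 5 rose (CCND1, CDK6, CDKN1A, CDKN1B and CDKN2D) and 1 fell (CDK4) of 12, or 5 and 1 adjusted over the list alone (6 and 0 with equal sums, 5 and 1 after GC correction). CDK6 rose from 6.76 ± 0.4964 to 22.8 ± 0.91 FPKM. Of genes of fatty acid synthesis and lipid storage 7 rose and 10 fell of 23, or 7 and 10 adjusted over the list alone (11 and 8 with equal sums, 5 and 9 after GC correction). Of ferroptosis and iron genes 3 rose (AIFM2, CHAC1 and SLC3A2) and 8 fell of 19, or 3 and 9 adjusted over the list alone (8 and 6 with equal sums, 3 and 8 after GC correction). That list passed camera on recovered fragments (limma-voom, Benjamini-Hochberg adjusted p = 0.0211). Of regulators of DNA methylation and Polycomb 8 rose and 5 fell (HDAC1, HDAC2, PHC2, SIRT1 and UHRF1) of 26, or 8 and 5 adjusted over the list alone (10 and 3 with equal sums, 8 and 5 after GC correction). Of replication-dependent histone genes 3 rose (H2BC21, H2BC4 and H4C8) and 1 fell (H2BC12) of 8, or 3 and 1 adjusted over the list alone (5 and 0 with equal sums, 3 and 0 after GC correction). H2BC21 lost its call without a filter (limma, Benjamini-Hochberg adjusted p = 0.0632) and with median-ratio rescaling (0.0619), and H2BC12 with equal sums (0.358). H4C8 lost its call when either shMock library was left out. The 21 lists that did not pass camera had Benjamini-Hochberg adjusted p between 0.0932 and 0.992, and members named here outside the 4 with the smallest p of their list were again chosen after their values were seen. Of these, KRT18 and S100A4 rose rather than fell with quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0283 and 0.0163).

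Among cell type markers, of the neuroendocrine list 2 rose (CHGA and ENO2) and 3 fell (CHGB, DDC and UCHL1) of 6, or 2 and 3 adjusted over the list alone (3 and 3 with equal sums, 2 and 3 after GC correction). Of the ciliated and basal airway list 3 rose (KRT14, KRT15 and NGFR) and 0 fell of 5, or 3 and 0 adjusted over the list alone (4 and 0 with equal sums, 2 and 1 after GC correction). Of the alveolar list, which holds markers of both alveolar cell types, 2 rose (CAV1 and LAMP3) and 0 fell of 5, or 2 and 0 adjusted over the list alone (4 and 0 with equal sums, 2 and 0 after GC correction). These 3 lists did not pass camera. The lists of fibroblast, leukocyte and endothelial markers had 2, 3 and 1 tested members and were not put to camera. The fibroblast markers COL1A1 and FBN1 did not pass, with log2 fold changes of 0.58 and 0.27. Of the leukocyte markers CD68 rose from 23.95 ± 0.66 to 113 ± 25.4 FPKM and ITGAM from 2.08 ± 0.18 to 6.29 ± 1.27 FPKM. CD14 fell from 6.34 ± 2.35 to 0.99 ± 0.00838 FPKM, and these calls were the same when adjusted over the list alone. The endothelial marker ESAM rose from 1.54 ± 0.0701 to 4.48 ± 1.38 FPKM, also when adjusted over the list alone.

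With 2 libraries per group, an exact permutation test of any 1 value cannot give a two-sided p below 0.33, so every call rests on limma's pooling of the spread across genes. By the recovered fragments, 4.6% and 4.2% of the shMock fragments and 13.5% and 11.9% of the shDUSP23 fragments lay outside the listed transcripts of known length.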

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

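The rescaling to equal sums, transcripts as features, protein-coding transcripts alone, voom on recovered fragments and the GC and length correction were chosen only after the data were seen; the other alternatives were planned. DUSP23 stayed past the limma threshold in every setting that tested genes, with a log2 fold change between -3.87 and -3.41 apart from single-library omissions. Genes changed at least 2-fold numbered 1627 with a mean of at least 5 FPKM, where fewer genes were tested. With TPM-type rescaling 5374 genes were higher and 1682 lower. This follows from the rescaling with the filter and pseudocount applied anew, which moved the median of all tested genes from 0.03 to 0.37. With transcripts as features 1554 changed, 636 higher and 918 lower, 1395 of them at least 2-fold; the cause was not tested. Camera with an estimated correlation called 0 lists against 25, 3 at an unadjusted p under 0.05 and 26 by fry. On simulated libraries, whose genes varied independently of each other, that form of camera found 0 of 5 shifted lists. With the replicate number as a block 6707 genes changed, but same-numbered libraries did not vary together (Pearson's r across genes 0.05, Spearman's rho 0.09; genes are not independent replicates), so the block has no pairing to rest on.

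Leaving out 1 library each, the lone library being assumed to vary like the other group, gave 3464 to 6442 changed genes, 1727 to 3234 higher and 1737 to 3208 lower, 1907 to 2905 at least 2-fold, a DUSP23 log2 fold change of -3.91 to -3.37, and 25 to 27 lists. The lowest counts came without shMock replicate 2 (3464) and without shMock replicate 1 (4038). Apart from camera with an estimated correlation, which ended all 25 list calls, 815 of 828 comparisons of lists with their alternatives kept direction and side of the threshold, 6 lost and 7 gained a call. The gained ones were TGF-beta targets with a mean of at least 5 FPKM (camera, Benjamini-Hochberg adjusted p = 0.0427) and without shMock replicate 1 (0.0271), YAP/TEAD targets without shMock replicate 1 (0.0436), ferroptosis and iron genes on recovered fragments (0.0211), glycolysis with the block and GC and length correction (0.0457), and pro-apoptotic genes with TPM-type rescaling (0.0347) and quantile normalization (0.0476). For the list members named by rule, 2841 of 2888 comparisons stayed, 40 lost and 7 gained a call and 0 reversed; calls were lost by ABCC4, CDKN2D, CLDN3, ESAM, H2BC12, H2BC21, H4C8, HES1, KRT15, LAMP3, MVP, NGFR and SPDEF. For the genes chosen after their values were seen, 1147 of 1364 stayed, 205 lost and 2 gained a call, and 10 reversed. The reversed ones, with their limma Benjamini-Hochberg adjusted p, were KRT18 (0.0283), S100A4 (0.0163), KRT7 (0.0544), ITGB1 (0.767) and IFIT1 (0.707) with quantile normalization, KRT7 with TPM-type rescaling (0.987), LIG1 with protein-coding transcripts alone (0.0213) and voom (0.0653), and SRGN with the GC and length correction (0.573, and 0.522 with the block); the cause was not tested. In simulated libraries where 200 of 13691 genes changed, changes of 0.5 on the log2 scale were recovered in 3.0% of genes, and 9 of 100 calls were false. Where 6161 changed, 3391 calls were made, 2.5% of them false, so changes can be missed. The real comparison gave 6202 calls. Simulated errors were independent between genes and drawn from the spread that limma fitted, so these false shares need not hold for the real calls.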

Other observations

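The tests of a shift of all genes and of leukocytes, those of GC content, length and abundance for the OXPHOS and mitochondrially encoded genes, and the genes named in the next paragraph, were chosen or changed only after the results were seen; the other tests were written before.

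Some genes best known from immune cells were higher in shDUSP23 beside ITGAX and CCL3L3, picked by their values and without a test of a list, whereas CD14 fell from 6.34 ± 2.35 to 0.99 ± 0.00838 FPKM. CCR7, a chemokine receptor of lymphocytes and dendritic cells, rose from 1.86 ± 0.28 to 15.6 ± 3.23 FPKM (log2 fold change 2.76). CD83 rose from 1.68 ± 0.43 to 9.95 ± 0.91 FPKM (log2 fold change 2.28). LAPTM5, a lysosomal membrane protein gene of blood cells, rose from 1.68 ± 0.65 to 11.1 ± 1.72 FPKM (log2 fold change 2.44). Some genes of stratified epithelia rose too: SBSN, suprabasin, rose from 4.78 ± 0.38 to 41.4 ± 7.31 FPKM (log2 fold change 2.98). LAD1, ladinin, rose from 1.06 ± 0.23 to 11.6 ± 1.94 FPKM (log2 fold change 2.95). ALOXE3, an epidermal lipoxygenase, rose from 4.57 ± 1.35 to 33.8 ± 2.23 FPKM (log2 fold change 2.78). IGFBP6, a binding protein of insulin-like growth factors, rose from 297 ± 2.82 to 1574 ± 303 FPKM (log2 fold change 2.39).

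The ribosomal protein, OXPHOS and mitochondrially encoded genes were lower in shDUSP23, with medians of -1.26, -0.85 and -1.06, and 3 technical explanations were considered. After correction for GC content and length the medians were -1.08, -0.61 and -0.64, and 56 of 56, 29 of 34 (85.3%) and 13 of 14 (92.9%) members that were lower before stayed lower, which argues against that trend as the whole cause but leaves it a part. The medians lay at least 0.88 below that of all tested genes (-0.88 for OXPHOS), a gap that 1 shift of all genes alike would not give. The lists were taken up because they lay below the other genes, so this gap restates that choice and is no separate support. The medians shrank to -0.51, -0.60 and -0.37 with quantile normalization, so their size depends on the scaling. Genes matched on level had medians of -0.58, -0.12 and -0.61, and 1000 random level-matched lists reached down to -1.15, -0.55 and -1.49. The ribosomal protein and OXPHOS medians lay below all of these, and 166 random lists fell as far as the mitochondrially encoded genes. The random lists were drawn gene by gene, whereas members of the 3 lists varied together (estimated correlation 0.827, 0.498 and 0.461). Their range is therefore too narrow to exclude abundance as the whole cause. Genes of like level fell less at the median than the lists. The gap passed the bound written for the test in the ribosomal protein and OXPHOS lists, but not in the mitochondrially encoded genes. For the ribosomal protein and OXPHOS lists it argues against abundance as the whole cause without excluding it. Abundance may account for part of the fall. For the mitochondrially encoded genes, whether it accounts for all of the fall stays open. A response to the loss of DUSP23, slower growth, a difference in the library batch and an effect of the construct itself stay open, untested.

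Leukocytes among the shDUSP23 cells are a candidate explanation for the immune cell genes. The test asked that 16 preset abundant leukocyte genes rise together to a median of at least 5 FPKM; the median of the 6 listed ones went from 2.2 and 2.25 FPKM in shMock to 8.06 and 7.36 FPKM in shDUSP23, past that bound, but they did not rise together and 10 of the genes were not listed, so it decides neither way. CORO1A and LCP1 stayed low, at no more than 0.662 FPKM in shDUSP23, which excludes nothing with 2 genes near the floor. Of the other 4, LAPTM5 and CD74 rose from 1.68 ± 0.65 to 11.1 ± 1.72 FPKM and from 2.77 ± 0.72 to 5.89 ± 1.49 FPKM, and S100A9 and SRGN fell from 74.7 ± 3.73 to 12.6 ± 4.87 FPKM and from 152 ± 5.405 to 114 ± 6.62 FPKM, with the CD74 call lost, among other alternatives, without shMock replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.137) and the SRGN call lost under several, turning higher without passing after the GC and length correction (adjusted p = 0.573). Leukocytes and a change within A549 cells both stay open.

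A shared rise of stratified epithelium genes was tested on a list of 64 genes written before their values were looked at. Only 31 of the 64 genes were listed, so the test speaks for a part of that list. Among the tested members 4 were also in the lists fixed before. Of 27 tested members 14 (51.9%) rose and 4 fell in limma, against 23.1% higher of all tested genes. The bound of 50% set in advance was passed by 1 gene, as such a program would give in the listed part. The unlisted genes have no values, so a program over the whole list stays open. After correction for GC content and length 12 (44.4%) rose, which is under that bound, against 21.8% of all genes, and with TPM-type rescaling 16 (59.3%) rose, against 35.9% of all genes. TRIM29 and COL17A1 rose from 9.73 ± 0.56 to 43.6 ± 6.11 FPKM and from 1.26 ± 0.24 to 7.44 ± 0.11 FPKM, whereas S100A9 and PERP fell from 74.7 ± 3.73 to 12.6 ± 4.87 FPKM and from 81.8 ± 3.13 to 45.1 ± 2.66 FPKM.

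A copy number difference between the shDUSP23 and shMock cells was tested along the chromosomes. The window of 100 neighbouring genes farthest from 0, on chromosome 17 from 45585871 to 57085022, had a median corrected log2 fold change of 0.42 (0.39 without the correction). Of 1000 shuffled gene orders 1 gave a window at least as large, so chance order rarely gives it, but the bound set in advance was to exceed all of them, and shuffling also breaks up neighbours that are regulated together; a copy number change there stays open.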
